A study of Homo sapiens and Mus musculus with 10 samples.

How the data were processed

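Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA bound by a protein and reads where it came from in the genome. The series holds 10 such libraries: 8 from MCF-7, a human breast cancer cell line of luminal type, and 2 from primary cells grown out of mouse mammary tumours. The antibodies were raised against TRPS1, a GATA-type zinc finger protein known as a transcriptional repressor, or against GATA3, a GATA-type activator of luminal breast cells. Per the labels' protocols, cells were fixed with 2 mM DSG for 35 min and then with 1% formaldehyde for 10 min. The untreated MCF-7 TRPS1 libraries used 5 µg of an R&D antibody, while the siRNA and mouse TRPS1 libraries used 10 µg of a Santa Cruz antibody, and all GATA3 libraries used 10 µg of another Santa Cruz antibody.

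The authors deposited 1 peak list per library, each line holding a chromosome, a start, an end, a peak name and a score. The aligner BWA, the peak caller MACS 1.4 and the builds hg19 (a human build) and mm9 (a mouse build) are named in the submitters' processing notes, without further settings. The score in column 5 is the authors' own value for each deposited peak; no header states its scale, and it was used here to describe, rank or filter peaks within a list. It was used across lists to give consensus sites a score and, as an alternative, to set a minimum of 70 in every list. Groups of consensus sites were therefore formed again from the rank of a peak within each list. Regions of high score in the guide libraries were picked by the sgScr score alone, and needed an sgTRPS1 peak of any score. The lists are named as filtered and intersected, but the filter and the second set of the intersection are not given in the sources used here. The lowest score was 50 in the mouse lists and in GATA3 replicate 2, and 70 in the remaining lists. Read numbers are not given in the sources used here, so the sequencing depth is unknown and the length of a list is the only measure of how much each library yielded. Every peak lay on an autosome or on chromosome X.

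Peaks were compared by position, with an overlap of at least 1 bp counting as shared. For the factors with 2 libraries, consensus sites were the merged regions that held a peak of both libraries, and their score was the lower of the highest peak scores in the 2 libraries. The similarity of 2 lists was measured by a Jaccard index. The number of overlapping peaks, averaged over the 2 lists, was divided by the summed list lengths minus that number. The mean index within an antibody was set against the mean between antibodies, with an exact permutation of the 4 untreated libraries over their 3 splits. The share of consensus sites at sites of the other factor was compared with 100000 circular shifts of the sites along their own chromosome, which keep their number, width and spacing (one-sided). A shift can place sites in stretches where no reads map, so a further placement moved each site by 10 to 50 kb, in 1000 draws.

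Each of the other conditions had 1 library, so no test across conditions was possible and the differences have no replicate check. For these the text gives list lengths and the share of control peaks with a peak in the other list, with exact Clopper-Pearson 95% intervals, which cover counting error only and treat neighbouring peaks as independent. Shares at sites of the partner factor were set against 10000 random sets of control peaks of the same size, drawn to match the score over 20 score groups, and the position among them is given as a percentile that describes these libraries. Because these sets also contain peaks at the partner sites, sets were further drawn with replacement from the peaks off those sites alone, with 20 and with 100 score groups. These further draws took the kept share of each score group as exact, so their spread leaves out the error of that share. The 2 replicates of a factor come from separate samples per the labels, but nothing says that they came from separate cultures, so the p-value of the library similarity measures only the spread between these samples, which may be technical. The p-values from shifted, displaced or reordered sites compare positions within the lists and measure no spread between samples.

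The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Overlaps were checked against bedtools 2.31.1 and gave the same counts. The overlap and shift steps were tested on simulated lists sized like TRPS1 replicate 1 against GATA3 replicate 1. The planted share was estimated as the excess over the mean share of 400 shifts, divided by 1 minus that mean. With 0%, 10% and 50% of sites planted at the partner, the estimates were 0.0663%, 9.98% and 49.97%.

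The rule for naming regions was fixed before the data were examined: genes from fixed lists and the genes nearest to the highest-scoring sites, or, with no annotation of the builds of the files, the 5 regions of highest score in each class by coordinates. The annotation at hand belonged to another human build, so no gene is named, and the planned steps on promoters and introns, GATA motifs and gene lists were not run. Coordinates are 1-based in hg19 or mm9. Alternatives fixed in advance were a reciprocal overlap of 50%, peak centres within 250 bp, the upper part of each list by median score, autosomes and X alone, control lists shortened to equal length, each replicate left out, the union of both libraries, replicate pairs, and other lists to class sites. Chosen after the data were seen were a score minimum of 70 in every list, equally long lists for the similarity and similarity with each library left out. So were the displacement by 10 to 50 kb, the sgScr and siNT lists in place of consensus sites, the groups by rank and the sets drawn off the partner sites. The tests in the closing part on other observations were also chosen then. Planned among their values were the percentiles from sets of all control peaks and the equal-length shares kept with sgTRPS1 and siGATA3.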

Results

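Binding of TRPS1 and GATA3 was mapped by ChIP-seq in human and mouse breast cancer cells. In untreated MCF-7 cells each factor was profiled in 2 libraries. GATA3 was profiled again in MCF-7 cells that carried a CRISPR guide RNA against TRPS1 (sgTRPS1) or a scrambled guide (sgScr), and TRPS1 in MCF-7 cells that received small interfering RNA against GATA3 (siGATA3) or a non-targeting one (siNT), with 1 library each. TRPS1 was also profiled in 1 library of mouse tumour cells labelled as carrying TRPS1 insertions and in 1 library of such cells labelled as without them. The TRPS1 lists held 11257 peaks in replicate 1 and 26730 in replicate 2, and the GATA3 lists 16435 and 23295. The sgScr list was the longest with 29495 peaks, against 3352 for sgTRPS1. The siNT list held 2425 peaks and the siGATA3 list 294, and the mouse lists held 5290 peaks without insertions and 480 with them. Median peak widths in MCF-7 ran from 313 bp in siGATA3 to 600 bp in TRPS1 replicate 2 and both GATA3 replicates, and in mouse cells they were 325 bp without and 164.5 bp with insertions. The protein or transcript levels of TRPS1 and GATA3 were not measured in these libraries, so the depletion itself was not checked here.

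The first comparison asked whether libraries of the same factor resembled each other more than libraries of the 2 factors. TRPS1 and GATA3 occupied largely overlapping sets of regions in untreated MCF-7 cells. Nearly the whole TRPS1 replicate 1 list, 98.6% of its peaks, lay at peaks of replicate 2, and 70.2% of GATA3 replicate 1 peaks lay at peaks of GATA3 replicate 2. The lists were deposited after an intersection with a set that is not named. If that set was another list of the series, such shares were in part fixed by the authors' processing. Between factors, 77.1% of TRPS1 replicate 1 peaks lay at GATA3 replicate 2 peaks and 54.1% at GATA3 replicate 1 peaks. The Jaccard index was 0.410 between the TRPS1 libraries and 0.410 between the GATA3 libraries. Across factors it ran from 0.282 to 0.417. The highest value came from the long lists of TRPS1 replicate 2 and GATA3 replicate 2, which shared 54.9% and 63.5% of their peaks. Unequal list lengths limit the index, as for the TRPS1 replicates, so this value does not show that these libraries were as alike as replicates. The sgScr GATA3 list reached 0.639 with GATA3 replicate 2 and 0.376 with replicate 1, against 0.289 and 0.416 with TRPS1 replicates 1 and 2. The mean within a factor exceeded the mean between factors by 0.0802 (exact permutation, one-sided p = 0.333, which is the smallest that 3 splits allow). The difference depends on list length, and was 0.199 with lists shortened to equal length, 0.0335 without GATA3 replicate 1 and 0.127 without GATA3 replicate 2.

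**Figure D1:**
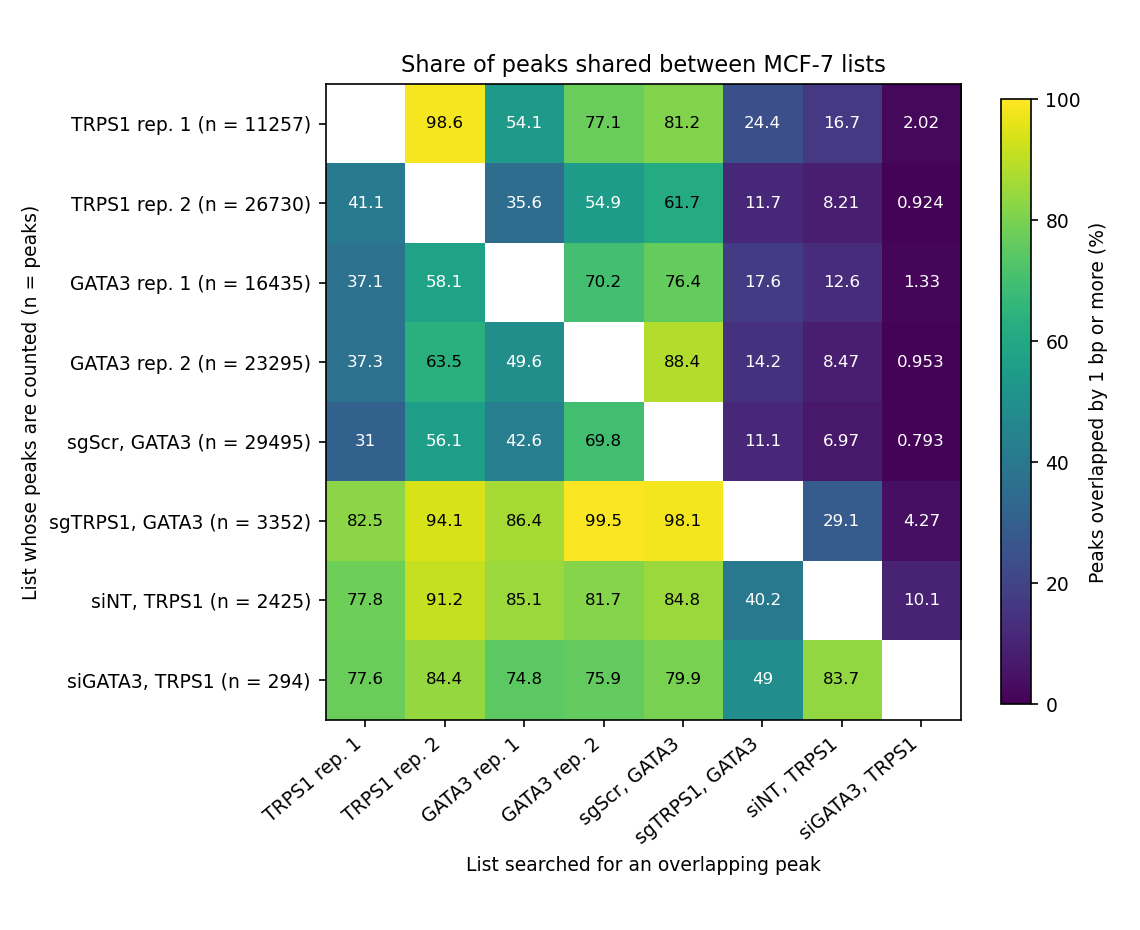
Each cell gives the percentage of peaks of the list named on the left that overlapped a peak of the list named below by 1 bp or more, for the 8 MCF-7 libraries, with the number of peaks per list in brackets. Of the sgTRPS1 peaks, 98.1% lay at sgScr peaks and 82.5% at TRPS1 replicate 1 peaks, and of the siGATA3 peaks 83.7% lay at siNT peaks and 74.8% at GATA3 replicate 1 peaks.

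Merging the replicates gave 10953 TRPS1 consensus sites with a median width of 857 bp and 11522 GATA3 consensus sites with a median width of 762 bp. A large part of each set was shared with the other factor. Of the TRPS1 sites, 5882 overlapped a GATA3 site, which is 53.7% (exact 95% interval 52.8 to 54.6%), and of the GATA3 sites 5904 overlapped a TRPS1 site, 51.2% (50.3 to 52.2%). Sites of highest score were the most often shared. Over 5 equal score groups, from the lowest to the highest, the share rose from 33.5% to 81.3% of TRPS1 sites and from 23.04% to 86.8% of GATA3 sites. Grouped by rank within each list instead, the shares went from 33.5% to 81.5% and from 28.6% to 87.5%. The centres of shared sites lay close together, with a median distance of 51 bp and 77.6% within 100 bp, against a median of 43 bp between shared peaks of the TRPS1 replicates and 42.5 bp between those of the GATA3 replicates.

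Circular shifts of the sites placed 0.693% ± 0.0915 (SD over 100000 shifts) of TRPS1 sites at GATA3 sites, so the observed share was 77.5-fold higher (one-sided permutation p = 1e-05, the smallest these shifts can give). For GATA3 sites at TRPS1 sites the shifted mean was 0.658% and the fold 77.9 (one-sided permutation p = 1e-05). Moving each site by only 10 to 50 kb left 1.98% of TRPS1 sites at GATA3 sites, 27.2-fold below the observed share. Neither placement keeps sites within regions open to many factors, and no list of an unrelated factor was compared. The folds and p-values therefore do not show that the overlap is particular to TRPS1 and GATA3. They also cannot allow for the unnamed set with which the deposited lists were intersected, which may have raised the overlap. The size of the share depended on the lists used. It was 32.9% of TRPS1 sites without TRPS1 replicate 1, which makes every peak of the longer replicate 2 a site, and 82.6% with the sgScr GATA3 peaks as the partner list, while 16.4% of GATA3 consensus sites held a peak of the short siNT TRPS1 list.

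**Figure D2:**
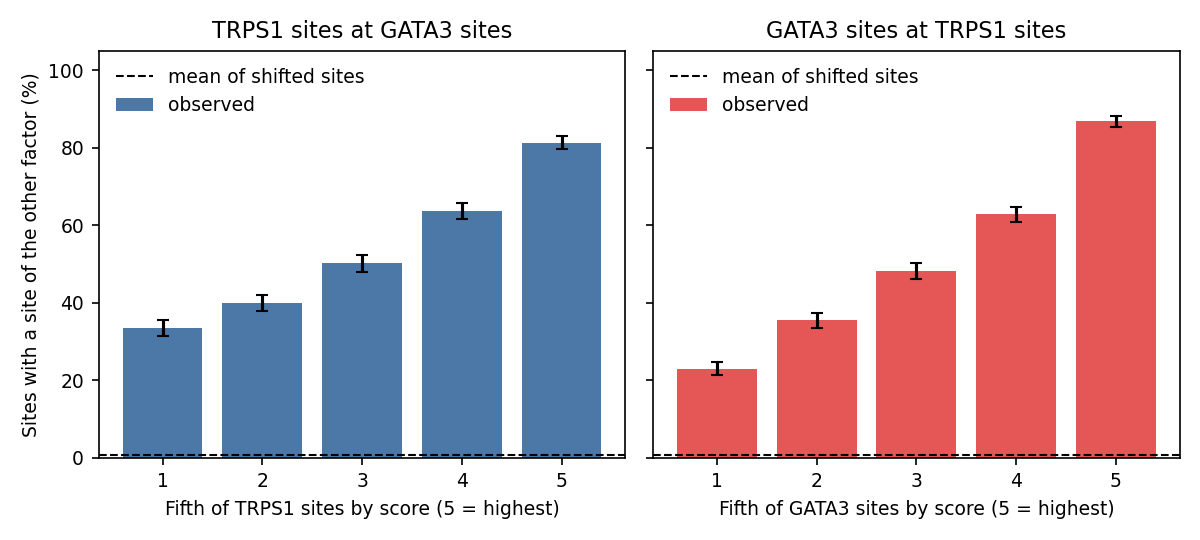
Bars give the percentage of TRPS1 consensus sites at GATA3 consensus sites and the reverse, by score group of the sites from 1 (lowest) to 5 (highest), with exact 95% binomial intervals; the dashed line is the mean over circular shifts. The share rose from 33.5% to 81.3% for TRPS1 and from 23.04% to 86.8% for GATA3, and the shifted means were 0.693% and 0.658%.

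The consensus sites were split by the number of libraries of the other factor with a peak there. A GATA3 peak was present in both libraries at 5870 TRPS1 sites (53.6%), in 1 library at 2840 (25.9%) and in neither at 2243 (20.5%). For GATA3 sites the numbers with TRPS1 were 5885 (51.1%), 2884 (25.03%) and 2753 (23.9%). The sites of 1 factor alone were weaker and narrower. TRPS1 sites had a median score of 208 and width of 951 bp with GATA3 in both libraries, and of 107 and 712 bp without GATA3. GATA3 sites had medians of 260 and 905 bp with TRPS1 in both libraries, and of 94.99 and 644 bp without it. Of the 2243 TRPS1 sites without a GATA3 replicate peak, 28.1% (26.3 to 30.0%) held a GATA3 peak in the sgScr library, and counting that library as well, 85.3% of TRPS1 consensus sites held a GATA3 peak in at least 1 list.

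The highest-scoring shared sites lay on chromosome 7 at 111799838 to 111801734 and on chromosome 8 at 8952889 to 8954136, 91924284 to 91927983, 128226905 to 128228783 and 135028434 to 135030383, all with a score of 3100. The siNT library also had a TRPS1 peak at each of these sites, and sgTRPS1 a GATA3 peak at each. Ties in score were ordered by position, so further shared sites may have the score of 3100. Among sites with TRPS1 and no GATA3 replicate peak, the highest scores fell on chromosome 15 at 71117098 to 71118097 (score 1384), chromosome 12 at 54687593 to 54688615 (1343), chromosome 2 at 204443384 to 204444465 (1147), chromosome 8 at 122176334 to 122176683 (963) and chromosome 3 at 114865921 to 114867333 (959). The regions on chromosomes 15 and 2 did hold a GATA3 peak in sgScr, and those on chromosomes 12, 8 and 3 held none in any of the 4 GATA3 lists. GATA3 sites without a TRPS1 replicate peak were led by chromosome 10 at 89248358 to 89249057 (score 1307), chromosome 21 at 44048194 to 44050562 (1204) and at 44707350 to 44708737 (1190), chromosome 4 at 86883634 to 86884828 (1143) and chromosome X at 1580633 to 1581527 (1023), in a stretch of 2.7 Mb where 0 of 27 GATA3 sites overlapped a TRPS1 site. These 5 regions held a GATA3 peak in sgScr and in sgTRPS1 as well, and the sites on chromosome 10 and at 44707350 on chromosome 21 also held a TRPS1 peak in siNT.

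The guide RNA libraries addressed whether GATA3 occupancy depends on TRPS1. The sgTRPS1 list had 8.80-fold fewer GATA3 peaks than the sgScr list. Of the 29495 sgScr peaks, 3282 had an sgTRPS1 peak, 11.1% (10.8 to 11.5%), and 26213 had none. Few of the sgTRPS1 peaks lay at places without a control peak, as 98.1% (97.6 to 98.5%) of them lay at sgScr peaks and 64 did not. The kept peaks came mostly from the stronger control peaks, with a median sgScr score of 2180 against 181 for the lost ones, and the kept share went from 0.0678% in the lowest to 50.2% in the highest of 5 score groups. Against the sgScr list shortened to the 3352 peaks of highest score, the kept share was 71.7%. With 1 library per guide these values describe the libraries.

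Counted as called peaks, the loss was not concentrated at TRPS1 sites. A peak of high score can lose signal and still be called, and such a loss would not be seen here. Of the 5899 sgScr peaks in the highest of 5 score groups, 4565 lay at TRPS1 consensus sites. Of the 9130 sgScr peaks at TRPS1 consensus sites, 29.7% (28.8 to 30.6%) had an sgTRPS1 peak, against 2.80% (2.58 to 3.04%) of the 20365 peaks elsewhere. Most of this gap followed the score, as random sgScr peak sets matched on score kept 29.0% on average, with a range of 28.3 to 29.6% over 10000 sets, and the observed share lay at percentile 100. Sets of the same scores drawn from the peaks off TRPS1 sites alone kept 25.96% on average, with 95% of them between 25.3 and 26.6%. Within the highest of the 5 score groups 55.8% of peaks at and 31.03% of peaks off TRPS1 sites were kept, and within the next group 6.38% and 3.29%. When peaks were classed by the siNT TRPS1 peaks the kept share was 46.7%, at percentile 51.6, and by the union of the TRPS1 replicates it was 18.6%, at percentile 73.8. The kept peaks of highest sgScr score lay on chromosome 12 at 33752544 to 33753243 and 45625644 to 45626243, chromosome 4 at 2207742 to 2208441, chromosome 7 at 107731691 to 107732340 and chromosome 2 at 213777210 to 213777859. The lost peaks of highest score lay on chromosome 12 at 97950094 to 97950743, chromosome 10 at 29393744 to 29394543 and 1401094 to 1401843, chromosome 8 at 105089479 to 105090178 and chromosome 18 at 59318602 to 59319401. All 10 of these regions held peaks of TRPS1 and of GATA3 in both untreated replicates. A score of exactly 3100 stood at rank 91 in sgScr, where 1110 peaks scored 3100 or more, so many peaks shared that value. No source used here says whether it is a ceiling, so the order of peaks at or above it may not reflect their strength. Score matching could not tell apart the peaks that share it either. The sgTRPS1 peaks of highest score without an sgScr peak were on chromosome 18 at 10443744 to 10444093, chromosome 6 at 83279715 to 83280264, chromosome X at 9973065 to 9973564, chromosome 13 at 70965043 to 70965392 and chromosome 7 at 156539186 to 156539685, and each held a peak in GATA3 replicate 2.

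**Figure D3:**
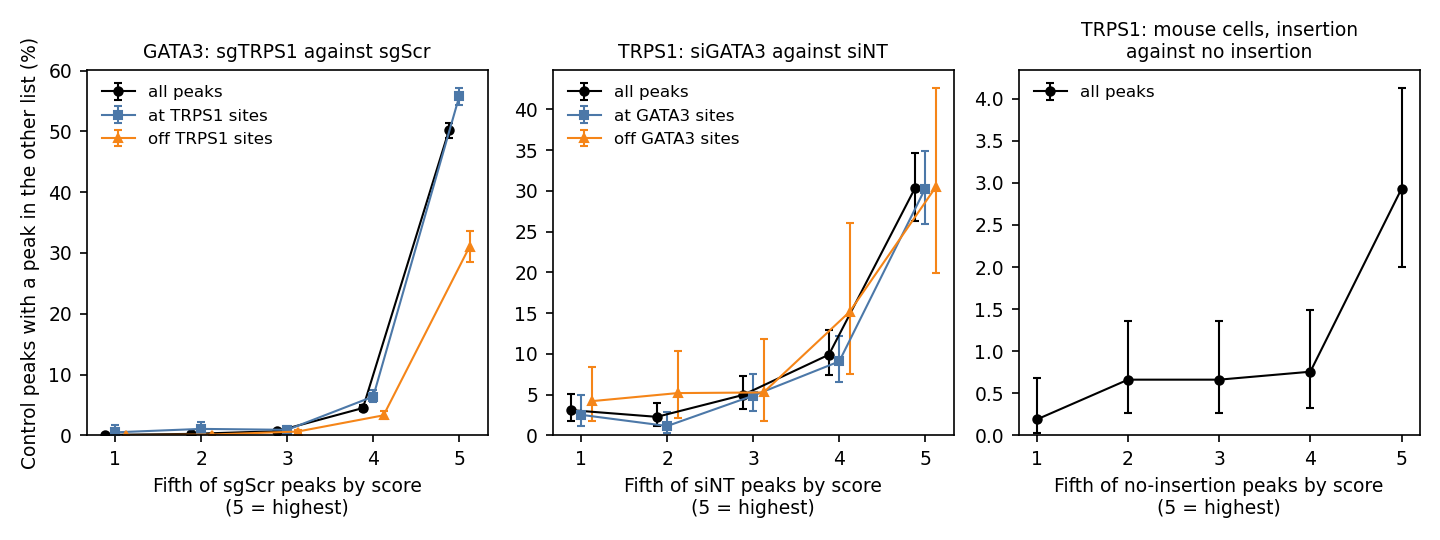
Points give the percentage of control peaks with a peak in the other list, by score group of the control peaks from 1 (lowest) to 5 (highest), with exact 95% binomial intervals; each vertical axis has its own range. Black points are all control peaks, blue and orange points those at and off consensus sites of the partner factor. In the highest group the kept share was 50.2% for sgTRPS1, 30.3% for siGATA3 and 2.93% for mouse cells with insertions.

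The siRNA libraries addressed the reverse question, whether TRPS1 occupancy depends on GATA3. The siGATA3 list had 8.25-fold fewer TRPS1 peaks than the siNT list. Of the 2425 siNT peaks, 245 had a siGATA3 peak, 10.1% (8.93 to 11.4%), and 2180 had none. Of the 294 siGATA3 peaks, 83.7% (78.9 to 87.7%) lay at siNT peaks and 48 did not. The kept share went from 3.09% in the lowest to 30.3% in the highest of 5 score groups, and against the 294 siNT peaks of highest score it was 41.2%. The siNT list was short and came from another TRPS1 antibody than the untreated libraries, but it lay largely at their sites, as 77.98% of its peaks were at TRPS1 consensus sites and 78.06% at GATA3 consensus sites.

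The kept share was 10.3% (8.97 to 11.8%) for the 1893 siNT peaks at GATA3 consensus sites and 9.40% (7.06 to 12.2%) for the 532 others. Within each of the 5 score groups it was lower at GATA3 sites than off them, from the lowest group to the highest 2.52% against 4.19%, 1.14% against 5.19%, 4.87% against 5.26%, 9.07% against 15.2% and 30.29% against 30.43%, with intervals that overlapped in every group. Score-matched sets of siNT peaks kept 10.97% on average, with a range of 10.0 to 11.8%, which put the share at GATA3 sites at percentile 0.66, and sets drawn from the peaks off GATA3 sites alone kept 13.4%, from as few as 11 such peaks in a score group. The position was percentile 0.51 with the union of the GATA3 replicates and 15.5 with the sgScr GATA3 peaks as sites. The kept peaks of highest siNT score were on chromosome 20 at 55310192 to 55310791, chromosome 5 at 17305950 to 17306549, chromosome 9 at 82104478 to 82105027, chromosome 12 at 104613764 to 104614313 and chromosome 8 at 128680763 to 128681362, and all 5 held peaks of both factors in the untreated replicates. The lost peaks of highest score were on chromosome 5 at 11350 to 11699, chromosome 20 at 55333692 to 55334291 and 45987892 to 45988291, chromosome 14 at 65693614 to 65694213 and chromosome 15 at 70755162 to 70755761. The region at 11350 on chromosome 5 held a peak in no other MCF-7 list, and the one at 45987892 on chromosome 20 only in GATA3 replicate 1. The siGATA3 peaks of highest score without a siNT peak were on chromosome 20 at 55839193 to 55839642 and 52402643 to 52402892, chromosome 7 at 56438952 to 56439201, chromosome 9 at 128092281 to 128092583 and chromosome 10 at 130262589 to 130262981, and of these the chromosome 9 region alone held a peak in another MCF-7 list.

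In the mouse tumour cells, the comparison asked how TRPS1 peaks differ between cells with and without TRPS1 insertions. The insertion list had 11.02-fold fewer peaks than the list without insertions, and the lists had little in common. The median score was 58.9 over a lowest of 50.01 with insertions, and 88.4 over a lowest of 50 without. Many insertion peaks thus lay little above the lowest score, so the small overlap does not show that TRPS1 bound elsewhere. Of the 5290 peaks without insertions, 55 had a peak in the insertion list, 1.04% (0.784 to 1.35%), and of the 480 insertion peaks 11.5% (8.75 to 14.7%) lay at a peak of the other list. Circular shifts placed 0.671 insertion peaks at the other list on average and 4 at most in 1000 shifts. Against the 480 highest-scoring peaks without insertions the kept share was 4.58%, and with a reciprocal overlap of 50% over the full list it was 0.473%. Kept peaks of highest score in the cells without insertions lay on chromosome 10 at 34228279 to 34228890, chromosome 15 at 101846401 to 101847590 and 61277650 to 61278475, chromosome 18 at 42926393 to 42926988 and chromosome 9 at 66468311 to 66468989. Lost ones lay on chromosome 15 at 39562815 to 39563825, chromosome 1 at 14474424 to 14475190 and 77457252 to 77457945, chromosome 4 at 150122112 to 150123047 and chromosome 3 at 135161702 to 135162350.

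The 5 highest-scoring peaks of the insertion list all fell within 186 kb of chromosome 15. Those at 50492152 to 50493303, 50653645 to 50654288, 50662279 to 50663528 and 50677525 to 50678583 each had a score of 3100 and no peak in the list without insertions. The remaining one, at 50496169 to 50496376 with a score of 1895, overlapped a peak at 50496220 to 50496475 in cells without insertions. The next score in the insertion list was 1568, on chromosome 17 at 4626153 to 4626616. The source of the high scores on chromosome 15 was not tested, so they cannot be taken as TRPS1 binding alone.

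**Figure D4:**
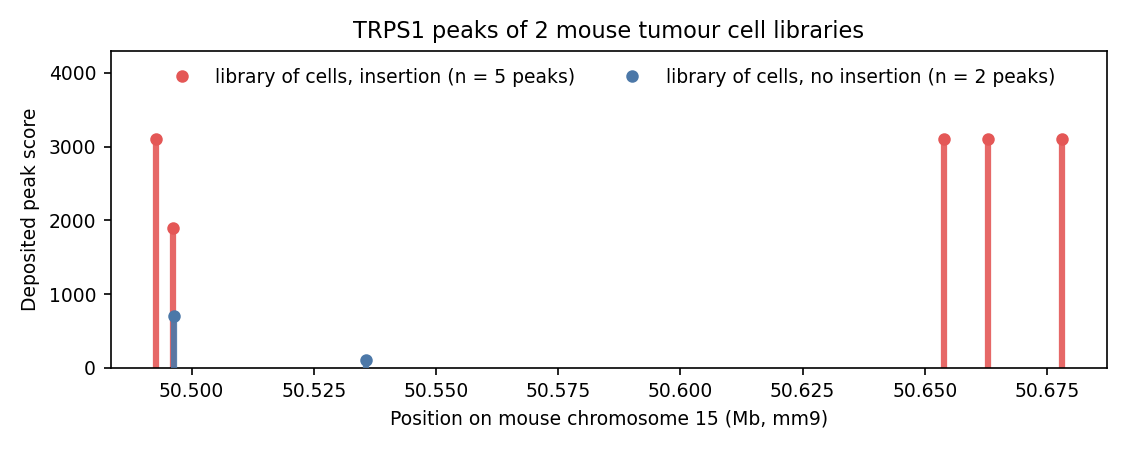
Vertical lines mark TRPS1 peaks by position on mouse chromosome 15 (Mb, mm9) and deposited score, in red for cells with TRPS1 insertions (n = 5 peaks) and in blue for cells without them (n = 2 peaks); scores compare peaks within a library only. Of the red peaks, 4 reach a score of 3100, and 1 of the 5 overlaps a blue peak.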

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

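The score minimum of 70, the sgScr and siNT lists in place of consensus sites, and the displacement by 10 to 50 kb were chosen after the data were seen. So were the sets drawn off the partner sites and, for the similarity, the equally long lists and the omission of each library. Classing control peaks by the sgScr and siNT lists, with sets drawn from all control peaks, was planned. The share of TRPS1 sites at GATA3 sites stayed above the shifted share with a permutation p of 0.001, the smallest 1000 shifts can give, under all 13 alternatives, with values from 32.9% to 82.6%. The reverse share did so under all 12, from 16.4% to 75.9%. Leaving out each replicate in turn gave 32.9% to 77.8% and 37.1% to 75.9%. The similarity difference stayed positive under 11 alternatives, from 0.0335 to 0.199, in a design that cannot reach significance. Replicates 1 and 2 of the factors share only a number. In the paired form, with a replicate block, the shares were 54.5% and 50.3% and the similarity difference 0.0602, and no call changed. Kept shares moved with a reciprocal overlap of 50% to 7.44% for sgTRPS1 and 0.473% for the mouse cells, and with control lists of equal length to 71.7% for sgTRPS1, 41.2% for siGATA3 and 4.58% for the mouse cells. The equal-length change follows from its construction, as weak control peaks leave the denominator; for the reciprocal overlap the cause was not tested. The percentile of the share kept at TRPS1 sites fell from 100 to 51.6 with siNT peaks and 73.8 with the TRPS1 union as sites, and that at GATA3 sites rose from 0.66 to 15.5 with sgScr peaks as sites. With sets drawn off the sites over 20 and 100 score groups, the percentile at TRPS1 sites was 100 and 100 for consensus sites, 99.995 and 84.2 for the union, and 88.3 and 73.5 for siNT peaks. That at GATA3 sites was 0 and 0 for consensus sites and for the union, and 26.1 and 0.04 for sgScr peaks. Score groups held as few as 11 and 1 peaks off the GATA3 consensus sites, 5 and 1 off the union, and 8 and 1 off the sgScr peaks. The draws took the kept share of such small groups as exact, so the percentiles at GATA3 sites are less firm than they look. Why the percentiles differed was not tested. Restricting to autosomes and X removed no peak. The promoter, motif and gene list steps and their alternatives were not run. Depth is unknown, so a missing peak shows only that it was not called at the depth of that library.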

Other observations

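The tests of explanations below were chosen after the results were seen. Some of the values they use were planned. These are the percentiles from sets of all control peaks, for each way to class sites, and the equal-length shares kept with sgTRPS1 and siGATA3. Shared TRPS1 and GATA3 sites were spread over 1851 windows of 1 Mb, and the fullest window, chromosome 10 from 29 to 30 Mb, held 19 of the 5870 shared sites. It was followed by chromosome 15 from 96 to 97 Mb and chromosome 4 from 102 to 103 Mb with 17 each. TRPS1 sites without GATA3 were most frequent on chromosome 8 from 8 to 9 Mb and chromosome 9 from 132 to 133 Mb, with 10 of 2243 sites each. Of the 48 siGATA3 peaks without a siNT peak, 58.3% (43.2 to 72.4%) held a peak in 1 or more of the 6 MCF-7 lists outside the siRNA experiment, against 92.7% (88.6 to 95.6%) of kept and 96.1% (95.3 to 96.9%) of lost siNT peaks. Of the 64 sgTRPS1 peaks without an sgScr peak, 87.5% (76.8 to 94.4%) held a peak in the 6 lists outside the guide experiment, against 99.9% (99.7 to 99.98%) of kept and 79.6% (79.1 to 80.1%) of lost sgScr peaks.

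GATA3 sites at the start of chromosome X lacked TRPS1, in a stretch picked because its windows held the most GATA3 sites without TRPS1. Its 2.7 Mb, which lie in the part that X shares with Y, held 27 GATA3 consensus sites, and 0 of them overlapped a TRPS1 consensus site or a peak of either TRPS1 replicate, against 44.7% of the 342 GATA3 sites on the rest of X at TRPS1 consensus sites. That these are weak GATA3 sites is argued against as the whole cause: with TRPS1 dealt out at random within score groups, the emptiest of all 10924 runs of 27 neighbouring GATA3 sites held 4.71 sites with TRPS1 on average and 1 at least over 10000 orders (one-sided permutation p = 0.0001, the smallest they can give, treating neighbouring sites as independent). Nor were all reads of the stretch removed from the TRPS1 replicates, because 7 peaks lay there, 2 in replicate 1 and 5 in replicate 2, beside 311 and 721 on the rest of X, with 35 and 42 beside 511 and 753 in the GATA3 replicates, 2 beside 36 in siNT, 1 beside 5 in siGATA3, 42 beside 945 in sgScr and 1 beside 110 in sgTRPS1. A partial loss of reads that map to both X and Y, and a true lack of TRPS1 at these sites, may each be the source, and the few peaks of the siRNA lists do not decide between them.

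The guide libraries shared 4 regions of high score that neither GATA3 replicate held. They lay on chromosome 11 at 5246332 to 5247381, chromosome 8 at 116616279 to 116617028 and 116631329 to 116632028 (each with a score of 3100 in both guide lists), and chromosome 6 at 74230555 to 74231154 (scores 2646 and 2786). Of the 2098 sgScr peaks scoring 2000 or more, these 4 alone lacked a peak in both replicates, and whether the replicate lists simply missed them was not tested. A candidate explanation is DNA present only in cells that received a guide, such as parts of the delivered construct, and this stays open: TRPS1 replicate 2, from cells without a guide, held peaks at 3 of the 4 regions, with scores of 86.3, 309 and 578, which ordinary binding at those places could give. No sequence of the constructs was used here, and no biological explanation was tested.

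The 8.80-fold shorter GATA3 list with sgTRPS1 may come from the removal of TRPS1 or from the library. A loss of called peaks confined to TRPS1 sites is argued against by the peaks elsewhere. Only 571 of the 20365 sgScr peaks off TRPS1 consensus sites, and 181 of the 12852 off the TRPS1 union, had an sgTRPS1 peak. The kept share at consensus sites lay at percentile 100 of score-matched sets, and was not below them with the siNT peaks or the TRPS1 union as sites (percentiles 51.6 and 73.8). That percentile compares kept shares and does not itself test confinement. Signal lost at peaks that were still called would not show. A single lower yield at all sites stays open: sgTRPS1 kept 71.7% of the equally long sgScr list, between the 56.1% and 83.7% that sgScr shared with GATA3 replicates 1 and 2 at 3352 peaks, but the 29.7% kept at TRPS1 consensus sites exceeded the 25.96% of score-matched sets off them, an excess seen again with the TRPS1 union over 20 score groups (percentile 99.995) but not over 100 (84.2), nor with siNT peaks as sites (88.3 and 73.5). At 3352 peaks sgScr also shared 53.5% and 53.2% with TRPS1 replicates 1 and 2. The 56.1% was thus little above the overlap with another factor, and exceeding it says little about yield. A general loss of GATA3 binding without TRPS1 cannot be told apart from a lower yield, since a high share of sgTRPS1 peaks at sgScr peaks (98.1%) follows from either, and guide and library are confounded with 1 library each. For siGATA3, the kept share at GATA3 sites lay at percentile 0.66 with consensus sites, 0.51 with the GATA3 union and 15.5 with sgScr peaks, and the equal-length share was 41.2%, against 27.6% to 36.7% between siNT and the untreated lists, of which 2 are GATA3 lists and 2 used another TRPS1 antibody.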
